A study of Escherichia coli with 15 samples.

How the data were processed

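The series holds 15 samples of ribosomal particles from Escherichia coli BLR (DE3) cells that lack the chromosomal copy of the DEAD-box helicase DbpA and express either its helicase-inactive R331A form or the wild-type protein. Per the labels' protocols, cells were grown at 37 °C and chilled with ice near an OD600 of 0.3. Particles were separated on density gradients, then treated with CMCT followed by sodium bicarbonate, with bicarbonate alone, with KMnO4 for 3 or 6 min, or not treated. CMCT forms adducts on uridine and guanosine bases, and the alkaline bicarbonate step removes most of them except those on pseudouridine. Libraries followed the randomer workflow of mutational profiling, in which a base that disturbs reverse transcription is read as a mismatch or deletion. The labels give R331A cells for all 35S and 45S particles and for the 30S KMnO4 libraries, and wild-type DbpA cells for all 50S particles and the untreated 30S library. Particle and genotype therefore change together in each comparison with 50S. The name of the untreated 30S file does not match its label, which was followed, so the identity and genotype of that library rest on the label alone.

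There were 18 files, 1 per sample and rRNA, with 12 for 23S and 6 for 16S rRNA. Per the file headers, the authors deposited, for each nucleotide, the count of reads with each mismatch and each deletion and the count of reads covering it (the depth). The deposited mutation rate is a fraction, which the authors obtained by dividing mismatches plus unambiguous deletions by depth. This was checked at every nucleotide of every file, with a tolerance of 1e-07. Deletions that the authors' header counts as ambiguous are in no nucleotide's count and were not used here. The aligner, the mutation caller, the quality filter and the reference sequence are not given in the sources used here. The 23S sequence in the files has 2909 nucleotides and the 16S sequence 1542, and the base of every listed 23S and 16S site was matched to E. coli numbering by short sequence anchors. All 25 listed 23S bases matched with the anchors, at an offset of 2 up to G1835 and of 4 from U1911, and all 11 listed 16S bases matched at an offset of 0. The 16S anchors lie at U516 and G1505, and 16S positions outside them keep the deposited number on the assumption that the offset of 0 holds there. In 23S rRNA, positions not enclosed by anchors of equal offset are named by base and deposited position, as in Gdep2826.

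Rates are given below in percent of reads, computed from the deposited counts. Replicated comparisons were fitted with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test on mutated reads with the logarithm of the depth at that position as offset. Positions needed a depth of at least 1000 in every library and at least 10 mutated reads over the libraries of the fit. Adjusted p-values are two-sided, by the Benjamini-Hochberg method over the positions tested, and a position was called at an adjusted p under 0.05. The contrasts of CMCT with bicarbonate, and the differences of that CMCT effect between particles, came from 1 fit of 9 libraries in 6 groups. There the spread comes from the 3 CMCT pairs, and each bicarbonate library is assumed to vary like them. CMCT libraries were compared between particles in a fit of the 6 CMCT libraries. The 16S fit had 3 libraries and 1 residual degree of freedom per position, so its spread comes from 1 CMCT pair, moderated across positions, and the 1 bicarbonate library is assumed to vary like that pair. Comparisons with 1 library per group had no test. There, rates are given with 95% Wilson intervals, and a position met the size rule when the intervals did not overlap and the rates differed by at least 2 percentage points. For KMnO4 the rule asked for at least 1 point after 6 min and for both KMnO4 intervals above the untreated one, so it counts rises only. A count of 0 allows up to 3 counts of the depth. Intervals and floors cover counting error only, and PCR reads without molecular identifiers are not independent molecules. Concentration of calls at known pseudouridines was tested by Fisher's exact test (two-sided) in scipy 1.17.1. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

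The named sites were fixed before the data were examined, as were the comparisons, tests and alternative settings, apart from those said to be added later. The 23S lists were the 10 pseudouridines, the 5 modifications on the base-pairing face (G745, G1835, U1915, G2445, A2503), 11 other modified nucleotides, and the 15 nucleotides of hairpin 92 (N2547 to N2561), which DbpA binds. The 16S list had 11 modified nucleotides. Off the lists, up to 10 positions per comparison could be named. In tested comparisons these had the largest difference in rate among called positions that differed by at least 1 point and had every replicate of a group on the same side of the other group. In untested comparisons they were the largest differences meeting the size rule. Any other off-list position was chosen after its values were seen and is said to be so.

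Alternatives were DESeq2 1.42.0, limma 3.58.1 on log2 odds with a pseudocount of 0.5, TMM factors on top of depth, mismatches only, deletions only, a sum over windows of 3 positions, a depth minimum of 5000, no minimum of mutated reads, the replicate number as a block, each CMCT replicate left out, a size rule of 5 points, and subtraction of the median of the same nucleotide. The fits were tested on simulated data with 200 changed positions, 50 per fold. Each simulated library had the pooled rate of each position and 1 common dispersion, with no general shift between CMCT and bicarbonate. The data have such a shift, a median log2 change of 1.05 in 35S and 0.96 in 16S. The simulated false calls therefore do not measure those of CMCT against bicarbonate in the data. For 35S CMCT against bicarbonate (2804 positions), edgeR recovered 2% of 1.5-fold, 10% of 2-fold, 62% of 4-fold and 4% of 0.5-fold changes, with 2 false calls among 41. For the CMCT libraries of 35S against 50S (2801 positions) it recovered 0%, 42%, 100% and 12%, with 5 false calls among 82. For 16S (1489 positions) it recovered 28%, 84%, 100% and 60%, with 2 false calls among 138. In the same order limma recovered 44%, 96% and 100% of 4-fold changes, with 15 false calls among 48, 5 among 73 and 17 among 153, and DESeq2 32%, 82% and 88%, with 0 false calls in each. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which can be technical. All 15 samples were used, and no raw reads were analysed here.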

Results

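Mutation rates were measured along 23S rRNA of 35S, 45S and 50S particles and along 16S rRNA of the 35S fraction and of 30S subunits. For each of 35S, 45S and 50S there were 2 libraries treated with CMCT and bicarbonate and 1 treated with bicarbonate alone. KMnO4 for 3 min, KMnO4 for 6 min and no treatment had 1 library each for 50S and for 30S. The median 23S depth of the CMCT libraries was 2258 and 2263 reads for 35S, 4964 and 6585 for 45S, and 7164 and 9195 for 50S. The bicarbonate libraries had 3144, 7346 and 4095 reads in the same order, and the KMnO4 3 min, KMnO4 6 min and untreated 50S libraries had 27571, 21428 and 38469. For 16S rRNA the 35S fraction had 13379 and 13309.5 reads with CMCT and 17897 with bicarbonate, and the 30S libraries had 61412, 53688 and 84986. At these medians a position with no mutated read could have a rate of up to 0.133% in the shallowest library and 0.00353% in the deepest. Median rates were 0.311% to 0.345% in the 23S CMCT libraries, 0.140% to 0.178% with bicarbonate and 0.100% in untreated 50S. The 35S and 45S particles came from cells with R331A DbpA and the 50S particles from cells with wild-type DbpA, so a difference from 50S can follow either.

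The comparison of CMCT with bicarbonate asks where each particle carries pseudouridine, on which the CMCT adduct outlasts the alkaline step. In 35S, 9 of the 10 listed pseudouridines rose with CMCT and U1915, which carries a methyl group on its pairing face, fell. U955 and U2580, both made by RluC, had rates of 24.4% ± 2.33 and 32.6% ± 0.0166 (SD, n = 2) with CMCT against 0.156% and 0.198% with bicarbonate, log2 changes of 7.27 ± 0.19 and 7.34 ± 0.15 (SE). The RluD sites U1911 and U1917 reached 1.31% ± 0.0396 and 4.21% ± 0.273 against 0.0255% and 0.0234%, rates that rest on 1 mutated read each. U1915 was at 9.74% ± 0.447 with CMCT and 15.8% (14.7 to 16.9) with bicarbonate, a log2 change of -0.70 ± 0.07 (edgeR adjusted p = 1.05e-11). The fall at U1915 was in mismatches, from 15.7% to 7.62%, while deletions rose from 0.0471% to 2.12%. With deletions only its log2 change turned to 5.43. All 10 pseudouridines were also called when adjusted over the list alone. On the pairing-face list, A2503 (2-methyladenosine, by RlmN) was higher, at 8.68% ± 0.0311 against 0.345%, G745 (1-methylguanosine, by RlmA) and U1915 were lower, and G1835 and G2445 did not pass, with 3 of 5 called when adjusted over the list alone. G745 went from 70.2% (68.3 to 72.1) to 51.3% ± 0.397. Of the 11 other modified nucleotides, C2501 (5-hydroxycytidine, by RlhA) and A1618 rose, which were 2 also when adjusted over the list alone. C2501 was at 7.96% ± 0.221 against 0.976%, and the A1618 call was lost without 35S replicate 2 (edgeR adjusted p = 0.154), with TMM factors, with mismatches only and with deletions only. In hairpin 92, 1 of 15 nucleotides was called higher, and 0 when adjusted over the list alone, and the median log2 change of the 15 was 0.72, below the 1.05 of all positions. No test was made of this median in any particle. Off the lists, the 3 largest differences were at U827, U813 and Adep73. None of them was called with TMM factors (log2 changes of 0.20, 0.41 and -0.37). U839 (1.55% ± 0.129 against 0.168%) and G2289 (1.17% ± 0.0777 against 0.169%) were among the 10 largest, but U839 was not called with mismatches only and G2289 with neither TMM factors nor deletions only. In all, edgeR called 593 of 2804 positions, 587 higher and 6 lower, while with TMM factors 111 were called, 39 higher and 72 lower. The median log2 change over all positions was 1.05 in 35S, 0.93 in 45S and 0.74 in 50S and with TMM factors 0.08, 0.05 and 0.02, so relative to that median U2580 was higher by 6.29 in 35S and U1915 stood at -1.75. With mismatches only, the calls at A2503 and U2457 in 35S were lost.

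In 45S the same question gave 9 pseudouridines called higher and U1915 called lower, and all 10 were called when adjusted over the list alone. U2580 reached 32.4% ± 0.0917 (SD, n = 2) against 0.257%, and U2504, in the peptidyl transferase centre, 11.9% ± 0.547 against 0.0973%. U1911 and U1917 were at 1.27% ± 0.186 and 2.47% ± 0.0682 against 0.135% and 0.103%. U1915 went from 10.6% (10.1 to 11.2) to 7.69% ± 0.092, a log2 change of -0.47 ± 0.05 (edgeR adjusted p = 4.18e-09). Deletions at U1915 rose from 0.0474% to 2.42%, and with deletions only its log2 change turned to 5.61. A2503 rose to 10.0% ± 0.0481 from 0.293%, and G745 fell to 53.1% ± 1.97 from 70.2%, so that with U1915 3 of 5 pairing-face sites were called, and 3 when adjusted over the list alone. Among the other modified nucleotides 5 were called higher, U747, A1618, U1939, C2501 and U2449, the last turning to -0.64 with TMM factors, and 8 when adjusted over the list alone. C2501 was at 11.9% ± 0.107 against 1.10%. None of the 4 calls other than C2501 held with TMM factors. The call at U747 was lost without 45S replicate 1 (edgeR adjusted p = 0.0564), those at A1618 and U1939 without 45S replicate 2 (0.105 and 0.0878), and that at U2449 without 45S replicate 1 or either 50S replicate (0.0767, 0.0605 and 0.0600). In hairpin 92, 6 of 15 nucleotides were called higher, and 6 when adjusted over the list alone, with a median log2 change of 1.02 over the 15, above the 0.93 of all positions. Off the lists, Gdep2826 was lower with CMCT, at 2.29% ± 0.19 against 3.97% (3.49 to 4.52), a call lost with DESeq2 and with deletions only. U827, Adep73 and U813 had larger differences but were not called with TMM factors (log2 changes of 0.08, 0.10 and 0.43). Cdep264, also with a larger difference, was not called with DESeq2. In all, 1224 of 2804 positions were called, 17 of them lower and the others higher (98.6%), and with TMM factors 289, of which 130 were higher and 159 lower. The count fell to 766 without 45S replicate 2.

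In 50S, the mature subunit, U955 had a rate of 26.2% ± 1.18 (SD, n = 2) against 0.134% and U2605, made by RluB, 7.0% ± 0.0201 against 0.0225%. U1911 and U1917 were at 4.02% ± 0.525 and 15.7% ± 0.552 against 0.121% and 0.131%. U1915 was at 60.5% ± 0.402 against 70.3% (69.0 to 71.5), a log2 change of -0.22 ± 0.04 (edgeR adjusted p = 0.000162), which DESeq2 did not call. Deletions at U1915 rose from 0.236% to 6.54%, and with deletions only its log2 change turned to 4.77. In total 9 of 10 pseudouridines were called higher and 1 lower, and 10 when adjusted over the list alone. On the pairing face, A2503 rose to 9.35% ± 0.76 from 0.318%, G745 fell to 52.4% ± 0.988 from 71.0%, and 3 of 5 were called in both adjustments, that over all positions and that adjusted over the list alone. C2501 rose to 28.0% ± 0.588 from 1.55%, a log2 change of 4.17 ± 0.13 (edgeR adjusted p = 1.34e-33). It was 1 of 4 other modified nucleotides called higher, with A1618, G2069 and U2449, the last pair turning to -0.47 and -0.40 with TMM factors, and 7 were called when adjusted over the list alone. The 3 calls other than C2501 were lost with DESeq2 and without a 50S replicate, A1618 without replicate 1 or 2 (0.113 and 0.0522), G2069 without replicate 2 (0.221) and U2449 without replicate 1 or 2 (0.0745 and 0.0692, edgeR adjusted p). In hairpin 92, 3 of 15 were called higher, and 3 when adjusted over the list alone, among them A2560 at 2.44% ± 0.213 against 1.21%, a call lost with TMM factors and with deletions only. The median log2 change of the 15 was 0.78, against 0.74 for all positions. Off the lists, the 2 largest differences, at Udep554 and Adep549, turned to log2 changes of -0.55 and -0.57 with TMM factors. A1916, which lies between U1915 and U1917, was at 2.54% ± 0.0806 against 0.0564% (0.0192 to 0.166), and was not called with deletions only. A2602 reached 1.39% ± 0.0757 against 0.0678% and U1621 1.34% ± 0.248 against 0.147%, both not called with mismatches only. In all, 587 of 2804 positions were called, 580 higher and 7 lower, and with TMM factors 195, of which 79 were higher and 116 lower. The count fell to 334 without 50S replicate 2, and with mismatches only the calls at A2503 and U2457 were lost.

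Whether these calls were concentrated at known pseudouridines was asked by Fisher's exact test (two-sided). In 35S, 9 of 10 known sites and 209 of 561 other uridines (37.3%) were called higher (exact p = 0.00103). In 50S these were 9 of 10 and 256 of 561 (45.6%, exact p = 0.0073). In 45S they were 9 of 10 and 386 of 561 (68.8%, exact p = 0.187), so no concentration passed the test there. Counting only calls of at least 1 percentage point, 5, 8 and 7 other uridines were called in 35S, 45S and 50S, and exact p was 1.19e-15, 1.44e-14 and 6.78e-15. Positions along 1 rRNA are not independent replicates.

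The CMCT minus bicarbonate signal of each pseudouridine was set on the scale of 50S to compare the size of the signal between particles. In 35S, U2580 stood at 1.01 ± 0.0313 of the 50S signal, U955 at 0.928 ± 0.0984 and U2605 at 0.958 ± 0.0468 (propagated SD, n = 2). U1911 and U1917 stood at 0.331 ± 0.0457 and 0.268 ± 0.0199 in 35S and at 0.290 ± 0.0617 and 0.152 ± 0.00692 in 45S. U2504 stood at 1.31 ± 0.195 in 35S and 1.47 ± 0.0687 in 45S, and U2604 at 0.852 ± 0.0426 and 0.726 ± 0.0598. The median over 9 sites was 0.881 in 35S and 0.899 in 45S. U1915 has no value, since CMCT lowered its rate in 50S. These ratios have no test of their own. They compare rates and were not shown to equal the share of molecules modified. The ratio of U2504 in 45S moved to 1.27 when summed over the position and its neighbours.

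**Figure D1:**
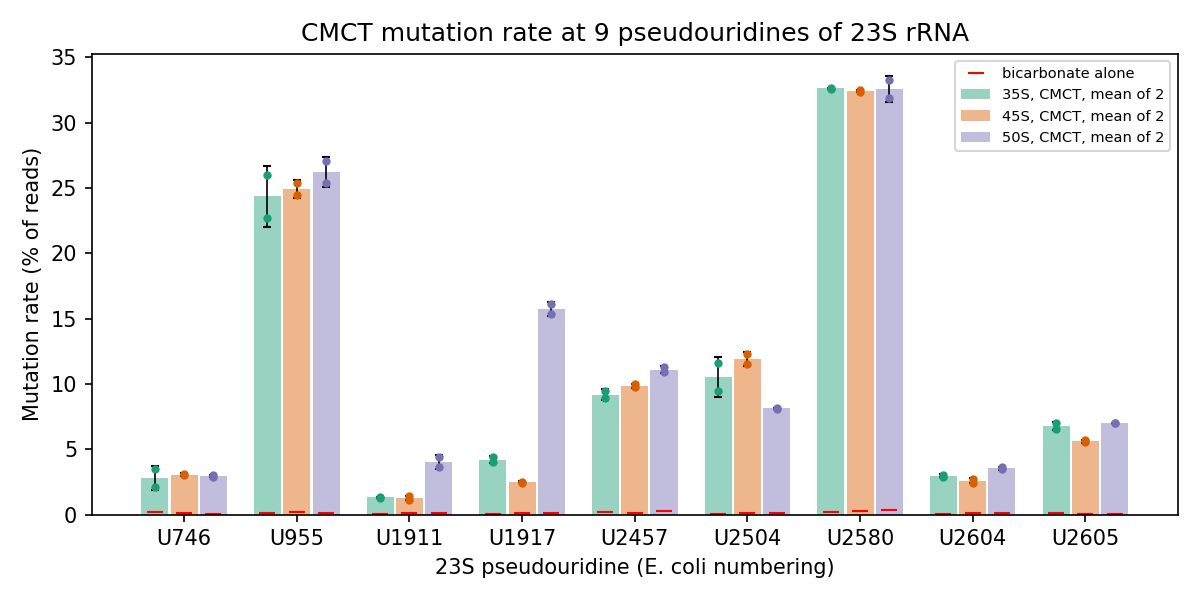
Mutation rate in percent of reads at 9 pseudouridines of 23S rRNA in CMCT libraries, as bars for the mean of 2 libraries with SD and points for each library, and red ticks for bicarbonate alone. U1911 and U1917 in 50S (4.02% and 15.7%) lie above 35S and 45S, while U2580 lies between 32.4% and 32.6% in the 3 particles.

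Comparing the CMCT libraries of 35S with those of 50S, the mutation rate was lower in 35S at the RluD cluster of helix 69 and at C2501. At U1915 the gap was also there with bicarbonate alone, 15.8% in 35S against 70.3% in 50S. It therefore cannot be read as a difference in CMCT adducts. U1915 had 9.74% ± 0.447 (SD, n = 2) in 35S and 60.5% ± 0.402 in 50S, a log2 difference of -2.63 ± 0.05 (SE, edgeR adjusted p = 4.16e-42). U1911 and U1917 differed by -1.60 ± 0.18 and -1.90 ± 0.09 (edgeR adjusted p = 3.54e-09 and edgeR adjusted p = 1.87e-24), and C2501 by -1.82 ± 0.08 (edgeR adjusted p = 4.13e-25). The pseudouridine list had 3 of 10 lower and 7 not called, with 5 when adjusted over the list alone. The pairing-face and other modified lists had 1 lower each, U1915 and C2501, and the same counts when adjusted over the list alone. U2504 was at 10.5% ± 1.56 and 8.14% ± 0.0424 and was not called. Off the lists, C1658 was at 0.511% ± 0.105 in 35S and 6.09% ± 0.0991 in 50S, a log2 difference of -3.58 ± 0.19 (edgeR adjusted p = 2.93e-21). A1916 was at 0.568% ± 0.06 and 2.54% ± 0.0806, with a sign that turned with deletions only. U813 was higher in 35S, at 4.81% ± 1.16 against 2.64% ± 0.317, and Cdep733 lower, at 0.139% ± 0.197 against 1.22% ± 0.0941, but neither was called with DESeq2 or limma. U813 was also lost without 35S replicate 1 or either 50S replicate (edgeR adjusted p = 0.393, 0.0748 and 0.464), and Cdep733 without 35S replicate 2 (0.0581). Of 2801 positions, edgeR called 10, 1 higher and 9 lower, and 17 without 45S replicate 1 or without 45S replicate 2. No nucleotide of hairpin 92 was called by edgeR (0 of 15, lowest adjusted p = 0.230, and 1 when adjusted over the list alone).

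The CMCT effect itself, the change from bicarbonate to CMCT, was compared between 35S and 50S by the interaction term. U1915 differed by -0.48 ± 0.08 on the log2 scale (edgeR adjusted p = 0.000486) and was the only position of 2804 called, with 233 at an unadjusted p under 0.05. In points of rate the change at U1915 was -6.03 in 35S and -9.79 in 50S, so the direction of this difference depends on the scale. DESeq2 called 0 and limma 5, without U1915, for which they gave -0.48 and -0.17. That call was lost without 35S replicate 1, 50S replicate 1 or 50S replicate 2, where the difference stayed at -0.43, -0.49 and -0.47 (adjusted p = 0.213, 0.0817 and 0.150), and its sign turned with deletions only, while 2 positions were called without 45S replicate 1 or 2. The effect at U1911 and U1917 differed by 0.55 ± 1.22 and 0.48 ± 1.02 (adjusted p = 0.963 and 0.966), and at C2501 by -1.15 ± 0.32 (adjusted p = 0.454), which limma called. The 35S bicarbonate library had 1 mutated read at U1911 and 1 at U1917, and that of 50S had 6 and 7. The log2 effects at these 2 sites thus rest on few reads. In points, the 35S signal was 0.331 and 0.268 of that of 50S. When adjusted over the list alone, 1 pseudouridine, 1 pairing-face site, 1 other modified nucleotide and 0 hairpin 92 nucleotides were called.

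Between the CMCT libraries of 45S and 50S, U1915 was at 7.69% ± 0.092 and 60.5% ± 0.402 (SD, n = 2), a log2 difference of -2.97 ± 0.04 (SE, edgeR adjusted p = 5.46e-48). With bicarbonate alone U1915 was at 10.6% in 45S and 70.3% in 50S, so its gap cannot be read as a difference in CMCT adducts. U1911 and U1917 differed by -1.68 ± 0.14 and -2.66 ± 0.08 and C2501 by -1.24 ± 0.06 on the log2 scale, all lower in 45S. U2504 was higher in 45S, at 11.9% ± 0.547 against 8.14% ± 0.0424 (log2 0.55 ± 0.08, edgeR adjusted p = 3.91e-06), a call lost with limma and with mismatches only. U2604 and U2605, neighbours modified by RluF and RluB, differed by -0.46 ± 0.12 and -0.32 ± 0.08 (edgeR adjusted p = 0.0472 and 0.0316). Neither was called with DESeq2 or limma. The U2604 call was lost without 45S replicate 2, 50S replicate 1 or 50S replicate 2 (edgeR adjusted p = 0.443, 0.825 and 0.642). That of U2605 was lost without 45S replicate 1 or 2 (0.136 and 0.0806) and without 50S replicate 1 or 2 (0.746 and 0.747). The pseudouridine list thus had 1 higher, 5 lower and 4 not called, and 6 when adjusted over the list alone. The pairing-face and other modified lists had 1 lower each, U1915 and C2501, which were 1 and 1 when adjusted over the list alone. Off the lists, C1658 was at 0.406% ± 0.165 in 45S and 6.09% ± 0.0991 in 50S (log2 -3.84 ± 0.14). A1916 differed by -2.07 ± 0.18, with a sign that turned with deletions only. Gdep2826 was higher in 45S, at 2.29% ± 0.19 against 0.540% ± 0.0266 (log2 2.09 ± 0.19, edgeR adjusted p = 2.09e-12), and was not called with deletions only. Of 2801 positions edgeR called 13, 3 higher and 10 lower, and with TMM factors 15, of which 2 were higher and 13 lower. Leaving out 35S replicate 1 or 2 gave 22 calls and leaving out 45S replicate 2 gave 20. In hairpin 92 edgeR called 0 of 15 (lowest adjusted p = 0.269), and 2 when adjusted over the list alone.

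For the CMCT effect, edgeR called 0 of 2804 positions between 45S and 50S, with 197 at an unadjusted p under 0.05, while DESeq2 called 0 and limma 2. Without 35S replicate 1 or 2 edgeR called 2 and 3 positions, and without 45S replicate 1 or 2 it called 1 and 7. U1911 and U1917 differed by -1.84 ± 0.68 and -2.33 ± 0.59 (edgeR adjusted p = 0.662 and 0.304), C2501 by -0.74 ± 0.25 (0.662) and U1915 by -0.25 ± 0.07 (0.304). The 2 calls by limma were U1917 and C2501. At U1917 the bicarbonate libraries of 45S and 50S had 11 and 7 mutated reads. Adjusted over the list alone, 3 pseudouridines, 1 pairing-face site, 0 other modified nucleotides and 0 hairpin 92 nucleotides were called.

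The CMCT libraries of 35S and 45S come from the same genotype, so their comparison sets particle against particle. U1917 was at 4.21% ± 0.273 in 35S and 2.47% ± 0.0682 in 45S (SD, n = 2), a log2 difference of 0.77 ± 0.11 (SE, edgeR adjusted p = 2.15e-05), which mismatches only did not call. C2501 was lower in 35S, at 7.96% ± 0.221 against 11.9% ± 0.107, a log2 difference of -0.58 ± 0.09 (edgeR adjusted p = 8.39e-05), lost with DESeq2 and without 35S replicate 1 (0.0697). U1915 was at 9.74% ± 0.447 and 7.69% ± 0.092, a log2 difference of 0.34 ± 0.06 (edgeR adjusted p = 0.0195). The U1915 call was lost with DESeq2 and without 35S replicate 1 or 2 (0.0973 and 0.590) or 45S replicate 1 or 2 (0.0764 and 0.0976), and its sign turned with deletions only. Gdep2826 was at 0.303% ± 0.00622 in 35S and 2.29% ± 0.19 in 45S (log2 -2.91 ± 0.30, edgeR adjusted p = 1.05e-09), a call lost with deletions only. Gdep580 was at 3.62% ± 0.0631 and 2.39% ± 0.393 (log2 0.58 ± 0.14, edgeR adjusted p = 0.0478) and was not called with DESeq2 or limma. Its call was also lost without 35S replicate 1 or 2, 45S replicate 1, or 50S replicate 1 or 2 (0.429, 0.302, 0.398, 0.208 and 0.221). These were the 5 calls of edgeR among 2801 positions, 3 higher and 2 lower, and with TMM factors 7 were called, 5 higher and 2 lower. The count was 2 without 35S replicate 1 and with DESeq2. The pseudouridine list had 2 higher and 3 when adjusted over the list alone, the pairing-face list 1 higher and 1, the other modified list 1 lower and 1, and hairpin 92 0 of 15 and 0. For the CMCT effect edgeR called 0 of 2804, with 160 at an unadjusted p under 0.05, DESeq2 called 0 and limma 2. U1917 differed there by 2.81 ± 0.95 (edgeR adjusted p = 0.733), a position limma called, and none of the 4 lists had a call when adjusted over the list alone. That difference at U1917 rests on 1 mutated read in the 35S bicarbonate library and 11 in that of 45S.

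**Figure D2:**
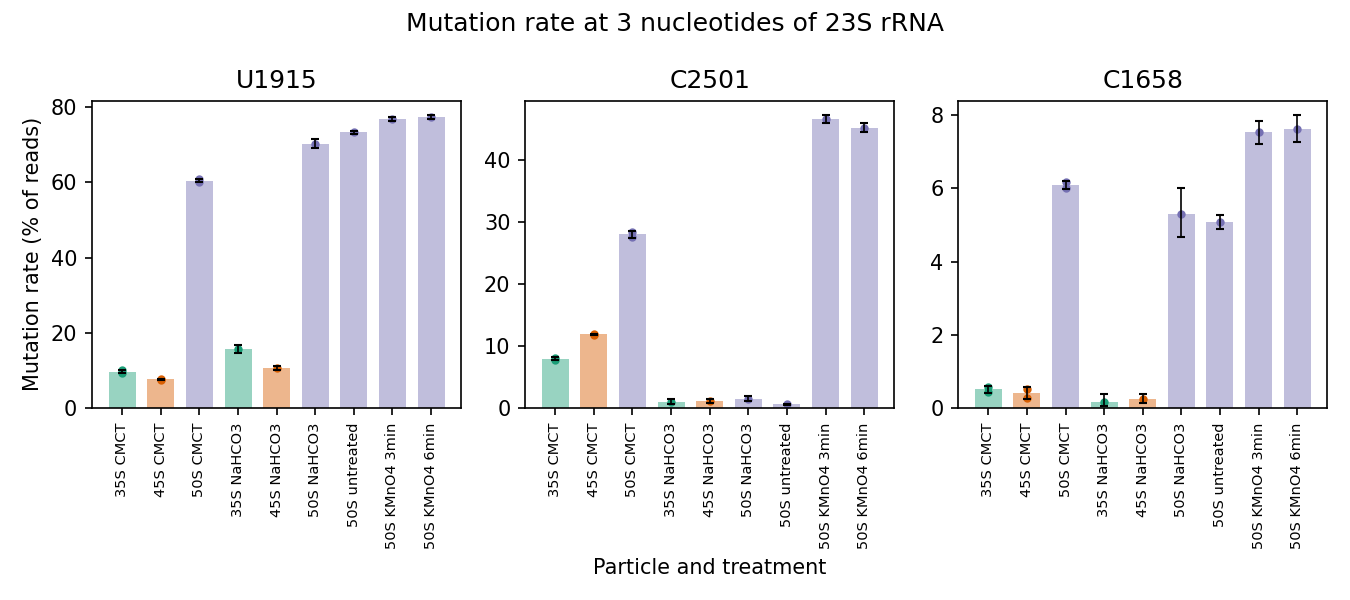
Mutation rate in percent of reads at U1915, C2501 and C1658 by particle and treatment, with bars for the CMCT mean of 2 libraries (SD) or the value of 1 library (95% Wilson interval) and points for each library. C1658 lies between 5.09% and 7.63% in the 50S libraries and between 0.165% and 0.586% in those of 35S and 45S.

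Bicarbonate alone reads modifications that disturb base pairing without an adduct, with 1 library per particle and so no replicate check. U1915 was at 15.8% (95% Wilson interval 14.7 to 16.9) in 35S, 10.6% (10.1 to 11.2) in 45S and 70.3% (69.0 to 71.5) in 50S, and it met the size rule in all 3 comparisons. C1658 was at 0.165% (0.0707 to 0.387), 0.244% (0.154 to 0.385) and 5.30% (4.67 to 6.01) and met it in both comparisons with 50S. Gdep2826 was at 3.97% (3.49 to 4.52) in 45S against 0.202% (0.0928 to 0.441) in 35S and 0.639% (0.426 to 0.957) in 50S. G745 did not meet the rule, at 70.2%, 70.2% and 71.0%, nor did C2501, at 0.976%, 1.10% and 1.55%. In all, 2 of 2835 positions met the rule between 35S and 50S, both lower in 35S. Between 45S and 50S 10 of 2838 did, 7 higher and 3 lower in 45S, and between 35S and 45S 7 of 2836, 1 higher and 6 lower in 35S. U1915, on both the pseudouridine and the pairing-face lists, was the only listed position among them, with 0 of 11 other modified nucleotides and 0 of 15 in hairpin 92.

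In 50S, bicarbonate was set against no treatment to ask what the alkaline step adds, again with 1 library each. G2069 (7-methylguanosine, by RlmK) was at 10.9% (9.82 to 12.0) after bicarbonate and 0.294% (0.252 to 0.341) without it. U2449, the dihydrouridine, was at 11.0% (9.81 to 12.2) and 0.0527% (0.0329 to 0.0844). With mismatches only the gains were 6.99 points at G2069 and 6.30 at U2449, and the difference at G745 was -1.87 points. On the pairing face 4 of 5 sites were lower after bicarbonate, G745 at 71.0% against 77.2%, G1835 at 58.0% against 63.9%, G2445 at 2.87% against 5.56% and U1915 at 70.3% against 73.3%. Off the lists, U1506 was at 12.8% (11.9 to 13.8) against 0.748% (0.668 to 0.838), Adep73 at 5.02% against 0.638%, and Udep554 at 25.6% against 43.4%. After bicarbonate T-to-C made 98.1% of the mutated reads at U1506 and A-to-T 100% at Adep73. Such single types can come from a sequence variant rather than a modification, which was not tested. U1506 was also raised after KMnO4, in libraries without bicarbonate, so its gain cannot be credited to the alkaline step alone. Of 2838 positions 25 met the size rule, 5 higher and 20 lower. The other modified list had 2 of 11 higher, the pseudouridine list 1 of 10 lower and hairpin 92 0 of 15.

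In 16S rRNA of the 35S fraction, CMCT raised U516, the pseudouridine made by RsuA, to 21.3% ± 0.737 (SD, n = 2) from 0.122% (0.0821 to 0.182) with bicarbonate, a log2 change of 7.43 ± 0.13 (SE). Its neighbour G515 went from 0.148% to 1.82% ± 0.306 (log2 3.62 ± 0.24, edgeR adjusted p = 1.42e-44). Of the 11 listed sites 2 were called, U516 and G966, and 1 when adjusted over the list alone. G966 (2-methylguanosine, by RsmD) was at 3.39% ± 0.063 against 2.62% (log2 0.37 ± 0.15, edgeR adjusted p = 0.0258), turned to -0.58 with TMM factors and was not called with DESeq2 or mismatches only. Not called were G527 at 25.7% ± 1.24 against 25.2%, U1498 at 49.5% ± 0.921 against 50.8% and A1519 at 22.1% ± 1.1 against 22.9%. Off the list, G1156 reached 2.61% ± 0.12 against 0.778%, A493 1.70% ± 0.159 against 0.346% and U1183 1.26% ± 0.0723 against 0.203%. In all, 1008 of 1489 positions were called, 1005 higher and 3 lower, and with TMM factors 410, of which 214 were higher and 196 lower. The median log2 change was 0.96, and 0.01 with TMM factors, so that U516 stood 6.48 above the median. This fit has 1 residual degree of freedom per position, so a replicate could not be left out with a test. These counts assume that the 1 bicarbonate library varies like the 1 CMCT pair, which no second library could check.

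The 16S bicarbonate library of the 35S fraction was also set against untreated 30S, where by the labels particle, treatment and genotype all differ. The untreated library has a file name that does not match its label, so each difference from it rests on that label. G527 (7-methylguanosine, by RsmG) was at 25.2% (24.5 to 25.8) against 0.836% (0.787 to 0.888), and deletions made 86.0% of its mutated reads after bicarbonate, so that mismatches only gave a gain of 2.79 points. In the 30S KMnO4 libraries, labelled R331A and without bicarbonate, G527 was at 1.34% after 3 min and 1.41% after 6 min. These values argue against the untreated label or genotype alone as the source of the gap at G527. Particle and treatment still differ together. U1498 (3-methyluridine, by RsmE) was at 50.8% (49.4 to 52.2) against 47.0% (45.9 to 48.1). Off the list, C419 was at 0.753% against 3.48%, G1514 at 4.39% against 2.30% and A1002 at 40.5% against 48.4%. U1021, C1010, C1006 and U1038 were also lower, U1021 at 36.7% against 46.2%. A-to-G made 99.9% of the mutated reads at A1002 in each library, and T-to-C 99.7% and 99.8% at U1038. Such single types can come from a sequence variant rather than a modification, which was not tested. Of 1521 positions 9 met the size rule, 3 higher and 6 lower, among them 2 of the 11 listed.

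KMnO4, an oxidant of pyrimidines, was compared with no treatment in 50S with 1 library per time. C2501 was at 0.660% (0.579 to 0.753) untreated, 46.6% (46.0 to 47.3) after 3 min and 45.3% (44.6 to 46.0) after 6 min. U1915 was at 73.3%, 76.8% and 77.4%, G2445 at 5.56%, 6.86% and 7.25%, and A2503 at 0.391%, 1.42% and 1.52% in the same order. The other 2 pairing-face sites fell, which the size rule does not count, G745 from 77.2% (76.7 to 77.6) to 70.6% and 69.6% (68.8 to 70.4) and G1835 from 63.9% (63.5 to 64.3) to 57.6% and 55.9% (55.2 to 56.6). Off the lists, G1223 went from 0.131% to 17.4% and 25.3%, Gdep2894 from 0.625% to 11.6% and 15.8%, and U1523 from 0.0947% to 9.25% and 10.9%. With mismatches only the gains after 6 min were 12.8 points at G1223, 9.08 at Gdep2894, 2.08 at U1523 and 0.468 at A2503. Of 2879 positions 735 met the size rule. These were 674 of 908 guanosines (74.2%, exact binomial interval 71.3 to 77.0), 46 of 631 cytidines (7.29%), 8 of 587 uridines (1.36%) and 7 of 753 adenosines (0.930%). The median gain after 6 min was 1.60 points at G, 0.362 at C, 0.187 at U and 0.115 at A. The rule was met by 1 of 10 pseudouridines, 3 of 5 pairing-face sites, 1 of 11 other modified nucleotides and 5 of 15 in hairpin 92, and subtracting the median of the same nucleotide left 198 positions and turned G2445 to -0.0193 points.

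In 16S rRNA of 30S, the KMnO4 libraries came, by their labels, from R331A cells and the untreated one from wild-type DbpA cells. The latter is the library whose file name does not match its label, so every gain in this paragraph rests on its label being right. G966 was at 2.34% untreated, 5.90% after 3 min and 7.79% after 6 min, and its neighbour C967 (5-methylcytidine, by RsmB) at 0.101%, 1.48% and 2.58%. U1498 was at 47.0%, 54.5% and 52.2%. These were the 3 of 11 listed sites that met the size rule, which counts rises only. A1519 fell from 24.6% (23.4 to 25.9) to 20.9% (19.4 to 22.4) and 19.4%. Off the list, G319 went from 0.0865% to 8.63% and 10.1% and G324 from 0.0889% to 6.28% and 8.37%. With mismatches only the gains after 6 min were 2.02 points at G966, 0.482 at C967, 4.66 at G319 and 3.43 at G324. Of 1522 positions 366 met the rule, 333 of 482 guanosines (69.1%, exact binomial interval 64.7 to 73.2), 28 of 353 cytidines (7.93%), 3 of 307 uridines (0.977%) and 2 of 380 adenosines (0.526%), and 69 did after subtracting the median of the same nucleotide.

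**Figure D3:**
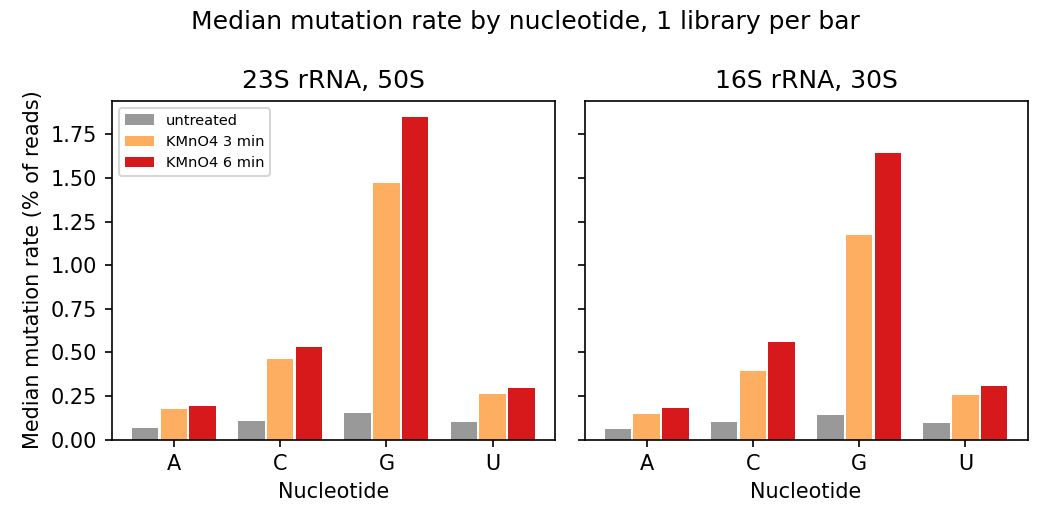
Median mutation rate in percent of reads by nucleotide in 23S rRNA of 50S and 16S rRNA of 30S, untreated and after KMnO4, with 1 library per bar and no error. Guanosines reach 1.85% in 23S and 1.64% in 16S rRNA after 6 min, the highest bars of each panel.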

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

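The tests on a common loss and on merging in this part were chosen after the fall at U1915 was seen, while the interaction term and its alternatives were fixed beforehand. The CMCT effect at U1915 differed between 35S and 50S by the interaction term, at -0.48 on the log2 scale (edgeR adjusted p = 0.000486), a difference between particles that also differ in genotype. Without 35S replicate 1, 50S replicate 1 and 50S replicate 2 the size stayed at -0.43, -0.49 and -0.47, while the adjusted p rose to 0.213, 0.0817 and 0.150, in fits with fewer libraries. DESeq2 gave -0.48 (adjusted p = 1.00) and limma -0.17 (adjusted p = 0.379), so neither called it. The direction depended on the scale. In points of rate the change from bicarbonate to CMCT was -6.03 in 35S and -9.79 in 50S, a larger fall in 50S. On log2 odds, the scale of limma, the difference was the -0.17 above. The size depended on the kind of change counted, at -0.67 for mismatches only (adjusted p = 1.14e-08, the lowest of the alternatives) and 0.65 for deletions only, an opposite sign, and was -0.74 with TMM factors.

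At U1915, the 3-methylpseudouridine, CMCT libraries had lower rates than bicarbonate libraries in 35S, 45S and 50S. Mismatches changed by -8.11, -5.32 and -16.1 points in that order, but deletions by 2.08, 2.38 and 6.30 points. The explanations below were weighed on both kinds of change together. A loss of mutated reads common to modified nucleotides was weighed with G745, G1835, G2069, G2445 and U2449. Their median log2 change lay above that of U1915 by 0.63 in 35S and 0.44 in 45S (SD of the 5 sites 0.20 and 0.28). In 50S the gap of 0.22 was within their SD of 0.31 and decides nothing. G2069 and U2449 gained their rates in the bicarbonate step and rose with CMCT in 45S by 0.17 and 0.24. The 45S gap rests partly on them, since G745, G2445 and G1835 changed there by -0.40, -0.26 and -0.03 against -0.47. A common loss thus stays open in 45S. In 35S G1835 changed by -0.07 against -0.70, which argues there against a loss of equal size at all modified nucleotides. That rests on G1835, since G2445 changed by -0.09 but varied widely with CMCT (2.70% ± 1.04), and G745 changed by -0.45. A loss shared by U1915 and G745 stays open in all 3. Merging of the U1915 mutation with one at U1917 in the same read was weighed by the relative fall against the U1917 rate. The fall exceeded that rate by 25.2 points or more in 35S and 45S, and lay -1.79 points from it in 50S. The excess argues against merging in 35S and 45S only if mutations at the 2 sites fall on molecules independently. Counts per position cannot show this, so merging stays open in all 3 particles. No biological explanation for the fall within each particle was tested.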

How the results depend on the processing

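One alternative, counting calls of at least 1 percentage point across the tested comparisons, was chosen after seeing the data, and all other alternatives were fixed beforehand. For the named sites, 2158 values were recomputed under the alternatives: 1884 kept direction and side of the threshold or stayed within their spread, 175 lost and 7 gained a call, 57 without a test moved by more than their spread and 35 reversed. That spread is the replicate SD for the signal relative to 50S, and counting error alone where each group had 1 library. Unless a value shows it, the cause was not tested.

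For CMCT against bicarbonate in 35S, 45S and 50S (593, 1224 and 587 calls), DESeq2 gave 99, 210 and 76, TMM factors 111, 289 and 195, mismatches only 132, 427 and 90, sums with neighbours 1601, 2154 and 1474, and the depth minimum of 5000 43, 65 and 34 of the 93 positions left. With limma 35S had 1093. Calls of at least 1 point were 24, 34 and 25. For 16S (1008 calls), DESeq2 gave 386, TMM factors 410 and the 1-point minimum 10. With each CMCT replicate left out in turn the counts were 423 to 600, 766 to 1263 and 334 to 660, the lowest for 45S and 50S being 766 without 45S replicate 2 and 334 without 50S replicate 2.

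For the CMCT libraries of 35S against 50S (10 calls), deletions only gave 6, limma 6, neighbours 22 and the depth minimum 0 of 93. For 45S against 50S (13), limma gave 7, neighbours 32 and the depth minimum 1. For 35S against 45S (5), DESeq2 gave 2, deletions only 1, neighbours 11 and the depth minimum 0. Leaving out a replicate gave 7 to 17, 9 to 22 and 2 to 6. These were 17 without 45S replicate 1 or 2 for 35S against 50S, 22 without 35S replicate 1 or 2 and 20 without 45S replicate 2 for 45S against 50S, and 2 without 35S replicate 1 for 35S against 45S. For the CMCT effect of 35S against 50S (1), DESeq2, deletions only and the depth minimum gave 0, limma 5 and neighbours 3, with 0 to 2 on leaving out a replicate: 0 without 35S replicate 1, 50S replicate 1 or 50S replicate 2, and 2 without 45S replicate 1 or 2. For 45S against 50S (0 by edgeR, 197 at an unadjusted p under 0.05), deletions only gave 1, limma 2, mismatches only 3 and neighbours 2, with 0 to 7 on leaving out a replicate: 2 and 3 without 35S replicate 1 and 2, 1 and 7 without 45S replicate 1 and 2. For 35S against 45S (0 by edgeR and DESeq2, 160 at an unadjusted p under 0.05), limma gave 2, and 0 to 0 were called on leaving out a replicate.

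With the replicate number as a block, the CMCT libraries gave 11, 14 and 4 calls against 10, 13 and 5, and the call at Gdep580 was lost (adjusted p = 0.0638), while no other named call changed. The numbers do not pair the samples by their deviations, which correlate at 0.0233, 0.0288 and 0.0260 between particles.

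For bicarbonate with the depth minimum of 5000, 0, 1, 0 and 2 positions met the size rule for 35S against 50S, 45S against 50S, 35S against 45S and 50S bicarbonate against untreated (2, 10, 7 and 25 otherwise), of 152, 812, 152 and 812 left. With 5 points, 2, 1 and 8 did in the last 3. For KMnO4 (735 in 23S, 366 in 16S), subtracting the median of the same nucleotide gave 198 and 69, and 5 points 17 and 6. By nucleotide in percent for 23S, mismatches only gave A 0.266, C 4.75 and G 59.9, the subtracted median C 2.69 and G 18.8, and 5 points A 0, C 0.158, G 1.43 and U 0.511. For 16S these were A 0, C 3.68 and G 52.7, then C 1.42 and G 12.7, then A 0, C 0 and G 1.04. The relative signal in 45S (0.899) was 0.846 without subtraction, 0.808 with mismatches only and 0.829 with neighbours, and 0.884 to 0.915 on leaving out a replicate, with 0.829 to 0.925 in 35S. The known pseudouridine test in 45S (exact p = 0.187) gave 3.79e-06 with mismatches only and 1.44e-14 with the 1-point minimum.

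Reversed log2 changes were, with sums over neighbours, U746 at -0.40, -0.34 and -0.39 in 35S, 45S and 50S, a window that holds G745. With deletions only they were U1915 at 5.43, 5.61 and 4.77, 0.65 for its CMCT effect and -0.19 for 35S against 45S, U813 at -0.93 and A1916 at 1.76 for 35S against 50S, A1916 at 1.30 for 45S against 50S, and in 45S Gdep2826 at 0.11, G2215 at 0.84, G2163 at 5.92 and G2205 at 1.80. With TMM factors they were Adep73 at -0.37 and U2210 at -0.39 in 35S, U2449 at -0.64 in 45S, G2069 at -0.47, U2449 at -0.40, Udep554 at -0.55 and Adep549 at -0.57 in 50S, and in 16S G966 at -0.58, U85 at -0.27 and G1193 at -0.016. With mismatches only U2449 was at -0.17 in 45S and -0.12 in 50S. In points with mismatches only, Gdep546 was at -0.104 and Cdep1876 at -0.0258 for bicarbonate in 45S against 50S, Cdep1876 at 0.00464 for 35S against 45S, and Gdep546 at 0.219, Cdep1876 at 0.00957, A1735 at 0.0926 and C1726 at 0.189 for bicarbonate against untreated. G2445 after KMnO4 was at -0.0193 with the median subtracted.

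Not run with a test was leaving out a replicate of the 16S fit, which has no residual degrees of freedom then. Removing the minimum of mutated reads left the 23S bicarbonate contrasts with the same positions, so it tests nothing there. No group had 4 libraries for a check of single outlying values, and no comparison had 3 libraries per group for other splits of the samples. The depth limits 35S most, with floors at median depth of 0.0954% to 0.133%.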

Other observations

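The tests on C1658 in this part were chosen after its rates were seen, while the test on the kinds of change at guanosine was written before its result was seen.

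In CMCT libraries A1916, between U1915 and U1917, was at 0.568% ± 0.06 in 35S, 0.585% ± 0.112 in 45S and 2.54% ± 0.0806 in 50S (SD, n = 2), where A-to-G made 94.8% of its mutated reads, against 0.0878% in untreated 50S. Its 35S and 45S values are named here after they were seen. At A2503, next to U2504, deletions made 92%, 93.8% and 91.5% of the mutated reads in the CMCT libraries of 35S, 45S and 50S, and 31.3% in untreated 50S. At C2501, C-to-T made 86.4%, 88.1% and 89.8% of the mutated reads in the CMCT libraries of the same particles, and 73.6% after KMnO4 for 6 min in 50S.

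The following positions were named after their values were seen. U1506 had rates of 20.0% ± 0.0209, 19.1% ± 4.51 and 13.7% ± 0.0502 with CMCT in 35S, 45S and 50S, 11.2%, 10.5% and 12.8% with bicarbonate, 5.20% and 6.30% after KMnO4 for 3 and 6 min, and 0.748% untreated. T-to-C made 93.6% of its mutated reads in untreated 50S and 99.5% with bicarbonate in 35S. U827, also read as T-to-C, was at 6.50% ± 0.389 with CMCT and 4.87% with bicarbonate in 50S, and at 1.06% untreated. The single types at U1506 and U827 can also come from a sequence variant, which was not tested. Gdep2826 was at 3.97% with bicarbonate in 45S and at 0.552%, 2.77% and 3.68% in 50S untreated and after KMnO4 for 3 and 6 min. G1723 lay at 64.7% to 70.4% in all 23S groups, those with no treatment included. G-to-A made 99.98% of its mutated reads in untreated 50S, so a sequence variant rather than a modification may set this rate, which was not tested. In the 35S fraction, the median depth of 16S was 5.93, 5.88 and 5.69 times that of 23S rRNA in the 3 libraries.

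C1658 was mutated at 5.09% to 7.63% in the 6 libraries of 50S and at 0.165% to 0.586% in the 6 of 35S and 45S, 1 of 2 positions among 2804 apart by at least 1 point, the other being U1915. The lowest of the 50S rates, 5.09%, is that of the untreated library. A single sequence variant in the wild-type strain is argued against by the mixed changes, since the leading type made at most 61.8% of mutated reads in any 50S group, with C-to-G at 49.1% and C-to-T at 43.5% untreated. Particle maturity and cell genotype cannot be told apart for C1658, because 0 of the 35S and 45S libraries came from wild-type DbpA cells. A change that follows the particle and one that follows the genotype thus both stay open, untested here.

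After KMnO4, guanosines gained more mutations than the other nucleotides in both rRNAs. The median gain after 6 min was 1.43 points at G and 0.398 at C in 16S, and 1.60 and 0.362 in 23S rRNA. Oxidised guanine read as T or C is a candidate explanation, with G-to-T and G-to-C together making 61.6% of the gain at G in 16S and 62.2% in 23S rRNA. Deletions made 27.9% and 28.2% of that gain and G-to-A 10.5% and 9.60%. An even spread over these kinds would already give G-to-T and G-to-C as much as the rest together. The share is therefore weak evidence for this explanation. At cytidines, C-to-T made 84.6% of the gain in 23S and 76.6% in 16S rRNA. In 16S rRNA the genotype changes together with KMnO4 by the labels. R331A libraries without KMnO4 exist there only for the 35S fraction. Their median rate at guanosines was 0.236% with bicarbonate and 0.446% and 0.479% with CMCT. In 30S it was 1.17% and 1.64% after KMnO4 for 3 and 6 min. These values argue against genotype alone as the source of the gain at G, although the particles differ. A part from genotype cannot be set apart. In 23S rRNA the labels give wild-type DbpA cells throughout. No biological explanation was tested.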
